A study of Mus musculus with 6 samples.

How the data were processed

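Total RNA was taken from whole hippocampus of C57B1/6J mice (as the labels spell the strain) at postnatal day 30, with 3 libraries of wild-type and 3 of PTCHD1 mutant mice. Per the labels' protocols, 2000 ng of total RNA was depleted of ribosomal RNA and made into stranded libraries by the dUTP method, and 4 libraries shared a lane of single-end sequencing. Per the submitters' processing notes, reads were aligned to mm9 with GSNAP and tested with DESeq2; versions and counting settings are not given in the sources used here. Groups were taken from the genotype label. Replicate numbers follow accession order and do not pair samples. The titles carry different numbers for each library, but nothing states that the libraries came from separate animals.

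The authors' deposited main table holds 35477 transcript rows with 25785 gene names and 6 columns of normalized signal. These values do not behave as read counts. In each library every value is a whole multiple of a library-specific step (100% of values within a tolerance of 0.01 of a step), and the multiples pile up at 42, 84 and 126, so the deposited signal was read as base coverage from reads of 42 bases divided by a size factor. No source used here states this unit, and printed read equivalents and the choice of limma rest on that reading. The steps ran from 0.759 to 1.42. The table also carries an unadjusted p-value and a score per transcript, both the authors'; the score has the sign of the change in the mutants. Transcript rows of 1 gene share coverage and are not independent. Mitochondrially encoded genes, fixed as 1 of 39 lists, had no matching row, and that list was not analysed here. All other per-sample columns were used, so 0 were left out.

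The deposited cell type, ontology, motif and binding tables give a fold enrichment (ratio) and a Bonferroni-corrected p-value per term, as the authors computed them. The corrected value of the motif tables exceeds 1 for many motifs and was read as a score, the p multiplied by the number of motifs without a cap, per the values deposited by the authors. Tables of motif pairs and of 2 further gene lists were not used. Some gene names in the ontology tables are written as dates and were left unmatched: 783 of 787 names in the lower table and 928 of 930 in the higher table matched the main table.

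The design fixed before the data were examined assumed read counts or normalized counts. Because the unit was read as coverage, a count model was not run, and limma on log2 values, set out beforehand for normalized values, was used. Coverage was divided by 42 to give normalized read equivalents. For each gene name the transcript with the highest mean was kept, a step not in the fixed design; a few rows carry only an identifier as name and were kept as genes. Genes with a mean of at least 10 over the 6 libraries were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), with Benjamini-Hochberg adjustment over 15717 genes and a threshold of 0.05. All tests are two-sided. Log2 changes are on the log2(value + 1) scale, which understates the change of low genes. With 3 libraries in each group, an exact permutation test of a single gene cannot give a p below 0.1, so significance rests on limma's pooled spread. The authors' p-values were also adjusted over the same genes.

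Gene lists (20) and cell type or tissue marker sets (19) were fixed before the data were examined. The 38 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the 38, and again with an estimated correlation and with fry, a rotation test of whether members move on balance 1 way. The named genes were Ptchd1, up to 10 genes per direction past the threshold with means of at least 50 and groups that do not overlap, up to 4 members of each list with the smallest p, and the leading 5 terms and 3 factors of the authors' tables. As only Ptchd1 passed, genes leading the authors' p-values were added after the data were seen. A second list of 24 choroid plexus genes was written from general knowledge after the data were seen. It served to examine the tissue explanation and is not independent of these data. Some genes that these rules select are not reported here.

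GC content and length came from GRCm38 transcripts (GENCODE M21) matched through RefSeq identifiers for 98.3% of tested genes. No coordinates are given, since that build differs from mm9. The correction subtracted from each library a spline fit (5 degrees of freedom each) of its deviations on GC and log2 length. The tests were run on simulated data of 15717 genes with 50 genes changed per fold size, which recovered 72% of genes changed 1.5-fold, 84% at 2-fold, 96% at 3-fold and 94% at 4-fold, with 16 false calls. Each simulated gene varied independently, whereas genes of the actual libraries vary together. These shares therefore do not give the recovery in the actual libraries. A list shifted by 0.3 was called, and so was 1 other of 38. A GC trend put into the data fell from a Spearman correlation of 0.633 to 0.0217 after correction, while a shift of 1 put into 200 genes came out at 0.987.

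Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom between 3.55 and 15.1, so none was merged. Alternatives covered scaling (quantile, upper quartile), the filter, the pseudocount (0.5 and 5), limma without a trend, other thresholds, the immediate early list left out, and each library left out in turn. Those added after seeing the data were the GC and length correction, robust empirical Bayes, library quality weights, voom, every transcript row, bases in place of read equivalents, and leaving out the libraries of strongest GC trend or of high choroid plexus markers.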

Results

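Gene expression was measured by sequencing of total RNA from whole hippocampus of mice at postnatal day 30. The series holds 3 wild-type libraries and 3 libraries from mice the labels call PTCHD1 mutants. Ptchd1 encodes a membrane protein with a patched domain, is carried on the X chromosome, and is known from human genetics as a gene for intellectual disability and autism. The comparison asks how the hippocampal transcriptome differs when this gene is mutated. Values are given as normalized read equivalents, which are the authors' normalized values of a transcript, read here from their steps as base coverage, divided by an inferred read length of 42 bases. Read equivalents summed over 1 transcript per gene came to 17830000, 23750000 and 18150000 in wild-type replicates 1, 2 and 3, and to 19010000, 16990000 and 12450000 in mutant replicates 1, 2 and 3, rounded to 10000. The labels do not give sex, litter or sequencing lane, and they do not state that each library came from a different animal, so p-values measure the spread between these samples. In all, 15717 genes passed the expression filter and were tested.

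Ptchd1 transcript was lower in every mutant library than in every wild-type library. It averaged 374 ± 45.5 normalized read equivalents in wild type and 154 ± 25.7 in the mutants (SD, n = 3 each). The mutant level was 41.0% of wild type, with a 95% interval of 33.1% to 50.9% from the limma fit. The log2 change was -1.28 ± 0.14 (SE), with an adjusted p of 0.0342. The single libraries held between 91.8 and 513 unnormalized read equivalents of Ptchd1, so transcript remained measurable in the mutants. The labels do not say which part of the gene was altered, and a value summed over the whole transcript does not show which exons the remaining coverage came from. The adjusted p rose to 0.0644 without wild-type replicate 1, to 0.371 without wild-type replicate 3 and to 0.223 without mutant replicate 2, while the log2 change stayed between -1.41 and -1.17 over all 6 omissions.

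**Figure D1:**
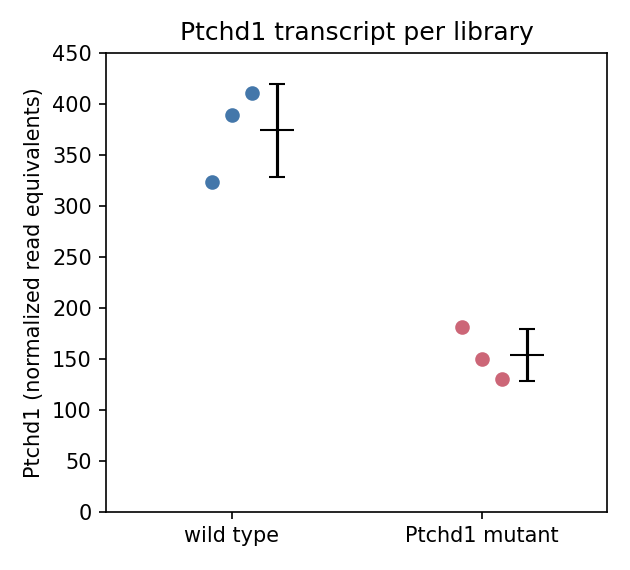
Ptchd1 in normalized read equivalents (vertical axis) for the 3 wild-type and 3 mutant libraries (points), with the group mean and SD beside them (black). The mutant libraries average 154 and the wild-type libraries 374, with no overlap.

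Beyond Ptchd1, many genes of synaptic transmission and neuronal excitability had higher values in the mutants, and many short genes of translation and respiration had lower values, with differences that were mostly small. No other gene passed the adjusted threshold of 0.05 in limma, where 0 genes were higher and 1, Ptchd1, was lower. At an unadjusted p under 0.05, 1416 genes were higher and 1525 lower in the mutants, against 786 in all that chance would give. Groups did not overlap for 24.3% of genes, where chance gives 10%. The next lowest adjusted p was 0.109, shared by a long run of genes. The authors' deposited table is less strict. Its p-values, adjusted over the same 15717 genes, gave 718 higher and 508 lower genes at 0.05, and each of these 1226 genes had an unadjusted p under 0.05 in limma. Leaving out mutant replicate 3 gave 21 higher and 23 lower genes in limma, and leaving out wild-type replicate 2 gave 1 higher and 36 lower. The 36 included Ptchd1 and choroid plexus markers such as Ttr, Kl, F5 and Otx2. Those markers were high in wild-type replicates 1 and 3 and low in wild-type replicate 2. Among settings chosen after the data were seen, library quality weights gave 462 higher and 343 lower genes, and leaving out the library of strongest GC trend in each group gave 18 higher and 92 lower. The latter setting also leaves out wild-type replicate 2.

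Among the genes that led the authors' deposited table (named after their values were seen), Egr1, an activity-regulated transcription factor, averaged 681 ± 72.0 in wild type and 1055 ± 80.2 in the mutants (SD, n = 3 each), a ratio of 1.55. Clip3, a cytoplasmic linker protein, averaged 1292 ± 121 and 1964 ± 194. Mapre3, a microtubule end-binding protein, averaged 1037 ± 28.8 and 1552 ± 203. Sncb, which encodes beta-synuclein, averaged 841 ± 88.3 and 1358 ± 229.8, a ratio of 1.60. In the other direction, Ndufa13, a complex I subunit, averaged 1129 ± 82.2 in wild type and 808 ± 14.8 in the mutants, and Derl1, of endoplasmic reticulum protein degradation, 990.4 ± 58.5 and 722 ± 31.6. Arl6ip1 averaged 4607 ± 166 and 3617 ± 250.2. None of these 7 genes overlapped between groups, and each had a limma adjusted p of 0.109.

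Genes of the presynaptic release machinery mostly had higher values in the mutants. Of 38 measured members of that list, 37 had positive log2 changes, with a median of 0.19. No member passed over all genes and 14 were higher when adjusted over the list alone, and 17 members were higher with no overlap between groups. Vamp2, a SNARE protein of vesicle fusion, averaged 2877 ± 66.3 in wild type and 3923 ± 379.5 in the mutants. The active-zone scaffold Bsn averaged 3862 ± 338 and 5717 ± 779. Mean log2 deviations of the list from the 6-library mean were 0.16, 0.13 and 0.02 in mutant replicates 1, 2 and 3 and -0.12, -0.12 and -0.07 in wild type. The list stood above other genes in camera with the preset correlation (adjusted p = 1.44e-11). With an estimated correlation its adjusted p was 0.356.

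The excitatory postsynapse showed the same direction with a smaller median of 0.08 over 45 members, of which 31 were positive, and 16 were higher when adjusted over the list alone. Examples were the scaffold Shank1, at 1401 ± 180.0 in wild type and 1987 ± 149 in the mutants, Shank2 at 1257 ± 171 and 1762 ± 207, Dlg4 (PSD-95) at 6047 ± 241 and 7687 ± 525, and the AMPA receptor auxiliary subunit Cacng3 at 428 ± 43.9 and 629 ± 79.5. The list was called by camera (adjusted p = 2.04e-05), and had an adjusted p of 0.356 with an estimated correlation. Calcium and sodium channel genes had a median of 0.14 over 29 members, 4 of them higher when adjusted over the list alone, and included Cacna1a, the P/Q-type calcium channel, at 1550 ± 116 and 1991 ± 171, and Cacna1i at 672 ± 13.1 and 892 ± 92.0. Potassium channel genes had a median of 0.09 over 38 members, with 5 higher and 1 lower when adjusted over the list alone. The camera adjusted p was 1.31e-05 for the former list and 0.000286 for the latter, and both had an adjusted p of 0.356 with an estimated correlation. Of 52 genes of autism and intellectual disability risk, 44 were positive, with a median of 0.12, and 6 were higher when adjusted over the list alone. This list shares synaptic genes such as Shank2 with the lists above. Its camera adjusted p was 2.34e-07, and 0.356 with an estimated correlation.

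**Figure D2:**
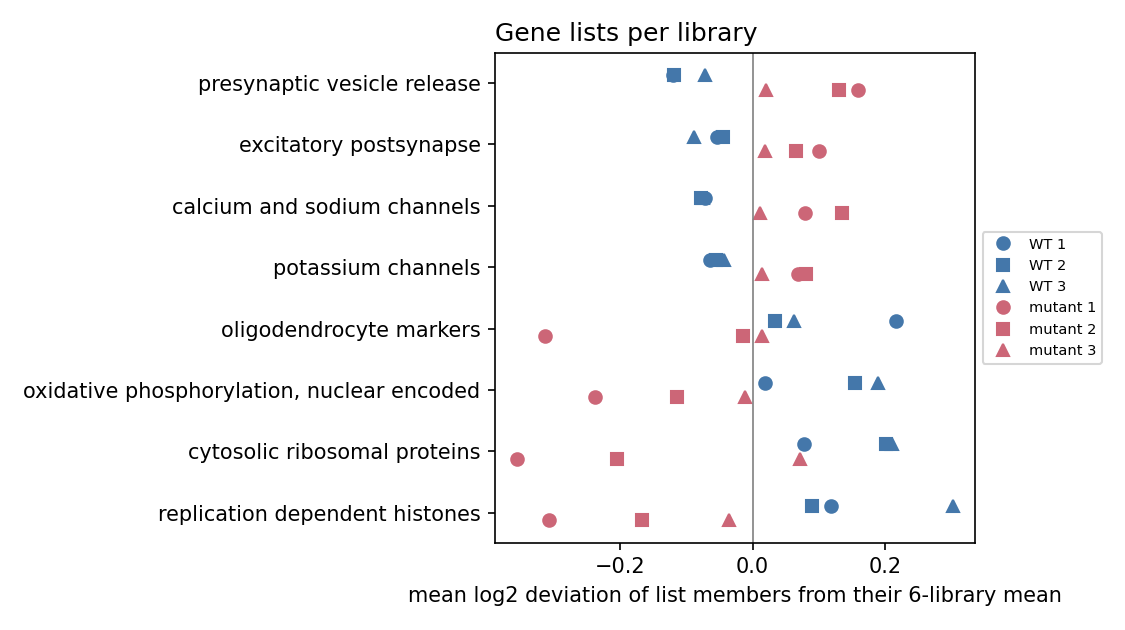
Mean log2 deviation of list members from their 6-library mean (horizontal axis) for 8 gene lists (vertical axis), with 1 point per library, wild type in blue and mutants in red. Mutant points lie to the right for the 4 synaptic and channel lists (presynaptic median log2 change 0.19) and mostly to the left for the ribosomal list (median -0.30).

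Inhibitory synapse genes went both ways and were not called (median 0.02 over 23 members, camera adjusted p = 0.3). Gabbr2, a GABA-B receptor subunit, averaged 3565 ± 47.2 in wild type and 4632 ± 571 in the mutants, while Gabrd, the delta subunit of extrasynaptic GABA-A receptors, averaged 255 ± 20.5 and 190.3 ± 25.9. The list of 39 immediate early and activity-regulated genes was not called either (median 0.04, adjusted p = 0.108), although 4 members were higher and 1 lower when adjusted over the list alone. Beside Egr1, Npas4 averaged 162 ± 20.6 and 234 ± 3.77, Nr4a2 940.1 ± 106 and 1376 ± 270.2, and Dusp6, a phosphatase acting on ERK, 1480 ± 51.5 and 1203 ± 78.4. Fos, named after its values were seen, averaged 359.6 ± 62.9 and 351 ± 51.7. Arc, named in the same way, averaged 2246 ± 352 and 2676 ± 183, with overlap between groups.

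Lists close to the presumed function of a patched-domain protein showed little. Hedgehog signalling was not called (median 0.05 over 19 members, camera adjusted p = 0.239), with the pathway repressor Sufu at 136.3 ± 10.1 in wild type and 187 ± 6.85 in the mutants, the receptor Ptch1 at 331 ± 42.1 and 394 ± 20.5, and Smo at 242 ± 18.6 and 203 ± 3.84. The 8 measured patched-domain and sterol-sensing genes had a median of 0.16 and a camera adjusted p of 0.032, led by Disp2 at 4944 ± 198 and 5911 ± 248. That call was lost with an estimated correlation (adjusted p = 0.356), after correction for GC content and length (0.454), with quantile normalization (0.0504), without the library of strongest GC trend in each group (0.129), and without wild-type replicate 2 (0.0656), mutant replicate 1 (0.0557) or mutant replicate 3 (0.0555). Cholesterol synthesis (median -0.08, adjusted p = 0.435) and retromer and endosomal recycling (median -0.05, adjusted p = 0.435) were not called. Glucocorticoid response genes had a median of 0.13 over 18 members, with 3 higher when adjusted over the list alone, among them Zbtb16 at 1362 ± 97.7 and 1689 ± 95.7. Their camera adjusted p was 0.0434, and 0.634 with an estimated correlation. It ended without wild-type replicate 2 (0.111), wild-type replicate 3 (0.364), mutant replicate 1 (0.125) or mutant replicate 3 (0.101), with quantile normalization (0.0504), at a mean of at least 50 (0.0687) and without the library of strongest GC trend in each group (0.357).

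Genes of the cytosolic ribosome and of oxidative phosphorylation had lower values in the mutants. Of 61 measured ribosomal protein genes, 9 were positive and the median log2 change was -0.30, with 22 lower when adjusted over the list alone. Rps3 averaged 4375 ± 298 in wild type and 3442 ± 183 in the mutants, and Rps14 925 ± 12.8 and 637 ± 146. Ribosomal protein genes have many processed pseudogenes, and how the authors placed shared reads is not given in the sources used here, so single values are uncertain. Of 66 nuclear-encoded oxidative phosphorylation genes, 7 were positive and the median was -0.21, with 23 lower when adjusted over the list alone, such as the ATP synthase subunit Atp5k at 335 ± 52.0 and 208 ± 21.4 and the complex III subunit Uqcrb at 341 ± 66.7 and 207 ± 33.3. The camera adjusted p was 1.75e-09 for ribosomal and 1.6e-09 for oxidative phosphorylation genes, and 0.356 for both with an estimated correlation. The mutant libraries differed among themselves. Mean log2 deviations from the 6-library mean were -0.36, -0.21 and 0.07 for ribosomal genes in mutant replicates 1, 2 and 3, against 0.08, 0.20 and 0.21 in wild type, and -0.24, -0.11 and -0.01 for oxidative phosphorylation genes, against 0.02, 0.16 and 0.19. Replication-dependent histone genes had a median of -0.38 over 36 members, with 6 lower when adjusted over the list alone (camera adjusted p = 0.000102). Hist1h1c averaged 391 ± 19.9 and 275 ± 35.9. The adjusted p for histones was also 0.356 with an estimated correlation. Heat shock proteins and chaperones were not called (median -0.05, adjusted p = 0.229), with the endoplasmic reticulum chaperone Hspa5 at 5099 ± 464 and 4240 ± 128 and Pdia4 at 1343 ± 88.5 and 1107 ± 33.2. Of their 28 measured members 13 were positive, among them Dnajb5 at 1303 ± 65.7 and 1515 ± 61.3.

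Base composition and length moved with the groups across these lists. Across genes, which are not independent replicates, the log2 change had a Spearman correlation of 0.359 with transcript GC content and 0.199 with transcript length. The median log2 change ran from -0.13 in the fifth of genes lowest in GC to 0.08 in the highest. Mutant replicate 1 deviated most in 1 direction (Spearman correlation of its deviations with GC 0.432) and wild-type replicate 2 in the other (-0.478). The remaining libraries deviated less, with -0.01 and -0.18 in wild-type replicates 1 and 3 and 0.01 and 0.08 in mutant replicates 2 and 3. After a correction for both properties, chosen after the data were seen, median log2 changes were 0.13 for presynaptic, 0.08 for excitatory postsynaptic, -0.17 for ribosomal protein and -0.09 for oxidative phosphorylation genes. They were 0.09 for calcium and sodium channels, 0.08 for autism and intellectual disability genes, 0.08 for glucocorticoid response, 0.07 for patched-domain and sterol-sensing genes, -0.24 for histones, -0.20 for ependymal markers and -0.06 for sex chromosome genes. The excitatory postsynaptic median was also 0.08 before correction, but the mean of that list fell from 0.12 to 0.08. For calcium and sodium channels the mean fell from 0.15 to 0.08. Among lists not called, the median turned sign for retromer and endosomal recycling (0.03) and moved to 0.06 for the inhibitory synapse, 0.02 for immediate early genes, 0.02 for hedgehog signalling, -0.03 for cholesterol synthesis, -0.02 for chaperones and -0.04 for genes near Ptchd1. Of the genes named here by their group means, the correction lowered the log2 change by more than 1.5 times for Bsn (0.56 to 0.32), Shank1 (0.51 to 0.27), Cacna1a (0.36 to 0.17), Cacna1i (0.40 to 0.19), Gabbr2 (0.37 to 0.24), Arc (0.26 to 0.17) and Disp2 (0.26 to 0.12). The same held for Atp5k (-0.68 to -0.44), Uqcrb (-0.71 to -0.37), Arl6ip1 (-0.35 to -0.23), Ugt8a (-0.28 to -0.13), Aspa (-0.52 to -0.27), Ddx3y (-0.33 to -0.12) and Fos (-0.03 to -0.01).

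Among cell type markers, those of oligodendrocytes had a median of -0.23 over 14 genes (-0.12 after correction for GC content and length), 3 of them lower when adjusted over the list alone. Ugt8a, an enzyme of myelin galactolipid synthesis, averaged 2110 ± 129 in wild type and 1740 ± 70.3 in the mutants, Trf 5433 ± 545 and 4407 ± 370.1, and Aspa 501 ± 27.9 and 356 ± 84.2. Their camera adjusted p was 0.000626, and 0.549 with an estimated correlation. The call ended (0.142) without wild-type replicates 1 and 3. The mean log2 deviation of the list from its 6-library mean was -0.31 in mutant replicate 1 and 0.22 in wild-type replicate 1, and between -0.01 and 0.06 in the other 4 libraries (-0.01 and 0.01 in mutant replicates 2 and 3, 0.03 and 0.06 in wild-type replicates 2 and 3). Pyramidal neuron markers had a median of 0.15 over 10 genes, including Camk2a at 20493 ± 1756 and 25037 ± 1910, with 1 higher when adjusted over the list alone. Their camera adjusted p was 0.00425, and 0.356 with an estimated correlation. After correction for GC content and length they passed fry (adjusted p 0.0101). Markers of CA1 (median -0.08), CA2 (-0.03), CA3 (-0.11) and dentate granule neurons (-0.08), GABAergic interneurons (0.08), astrocytes (-0.03), oligodendrocyte precursors (-0.0012), microglia (-0.09), endothelium (-0.03) and pericytes (-0.02) were not called in camera. Neither were those of blood (0.19), thalamus (0.18) and striatum (0.08). After correction for GC content and length, camera called dentate granule neuron markers lower (median -0.14, adjusted p = 0.00543) and GABAergic interneuron markers higher (0.11, 0.0323), both with an adjusted p of 0.636 with an estimated correlation, and the medians turned sign for CA3 (0.03), endothelium (0.08) and astrocytes (0.0001). They moved to -0.0031 for CA1, -0.06 for CA2, -0.03 for microglia, -0.09 for oligodendrocyte precursors, -0.07 for pericytes, 0.32 for blood and 0.13 for striatum. The neocortex set was called (median 0.08, adjusted p = 0.032). With an estimated correlation its adjusted p was 0.356, and the call also ended after correction for GC content and length (0.0552), with quantile normalization (0.0504), without mutant replicate 1 (0.0681) and without the library of strongest GC trend in each group (0.0801). Inflammation and complement genes had a median of -0.11 over 21 members and a camera adjusted p of 0.046, and 0.623 with an estimated correlation. That call ended without wild-type replicate 1 (0.468), mutant replicate 1 (0.0557), mutant replicate 2 (0.0619) or mutant replicate 3 (0.0953), with quantile normalization (0.072) and without wild-type replicates 1 and 3 (0.718).

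Choroid plexus transcripts, from the epithelium that makes cerebrospinal fluid beside the hippocampus, were abundant in some wild-type libraries. Ttr, which encodes transthyretin, stood at 48922 and 17849 normalized read equivalents in wild-type replicates 1 and 3, at 275 in wild-type replicate 2, and at 2199, 628 and 621 in the mutants. The 15 markers had a median log2 change of -2.24. They were lower in camera (adjusted p = 2.81e-06), with an adjusted p of 0.539 with an estimated correlation, and the direction reversed (adjusted p = 0.0247) without wild-type replicates 1 and 3. Ependymal markers (median -0.39, adjusted p = 0.0177) and meningeal fibroblast markers (median -0.45, adjusted p = 0.0038) were lower as well. Both had an adjusted p of 0.539 with an estimated correlation and of 0.235 without wild-type replicate 1, and both calls ended without wild-type replicates 1 and 3 (0.148 for ependymal and 0.464 for meningeal markers). The ependymal call also ended without mutant replicate 2 (0.0994). Without wild-type replicates 1 and 3, a choice made after the data were seen that leaves a lone wild-type library assumed to vary like the mutants, limma called 0 genes in either direction and Ptchd1 had a log2 change of -1.35.

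**Figure D3:**
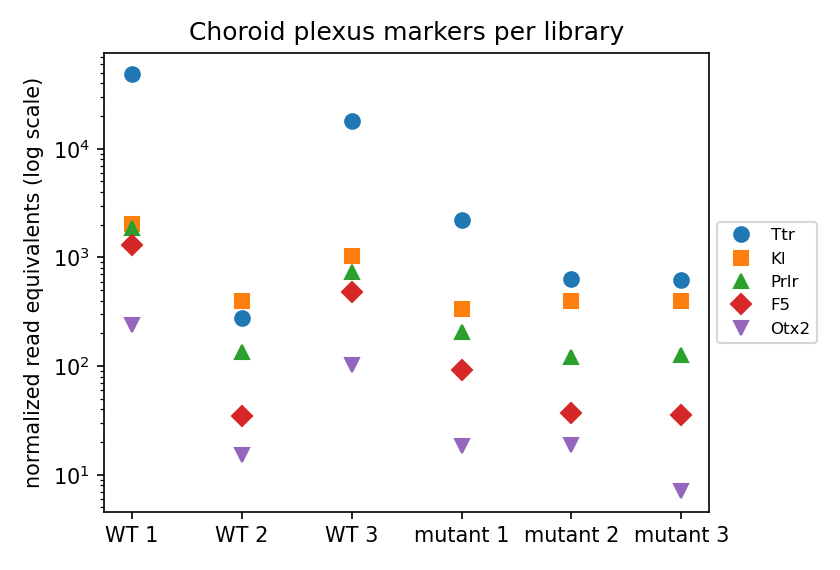
Normalized read equivalents (vertical axis, log scale) of 5 choroid plexus markers in the 6 libraries (horizontal axis), with 1 symbol per gene. Wild-type replicates 1 and 3 lie above the other 4 libraries for every gene, with Ttr at 48922 and 17849 against 275 to 2199.

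Genes near Ptchd1 on the X chromosome were not called as a list (median -0.12 over 20 members, camera adjusted p = 0.274). Of the 20, 7 had positive log2 changes. Acot9 averaged 215 ± 23.5 in wild type and 162 ± 13.2 in the mutants, and Prdx4 125 ± 5.94 and 89.4 ± 14.7. In the other direction, Klhl34 averaged 1095 ± 58.3 and 1266 ± 55.5, and Pcyt1b 863 ± 63.1 and 998 ± 51.8. Y-linked transcripts were present in all 6 libraries. Xist, added after its values were seen, lay between 15.4 and 38.8 in them, against 1794 to 2685 for Ddx3y. Each library thus had the pattern of male tissue. Ddx3y averaged 2483 ± 180.4 and 1980 ± 221, and Kdm5d 1056 ± 61.4 and 891 ± 67.6. The list of 6 measured sex chromosome genes was called in camera (adjusted p = 0.0434), with an adjusted p of 0.356 with an estimated correlation and of 0.17 after correction for GC content and length. It also ended without wild-type replicate 1 (0.136), wild-type replicate 2 (0.0541) or mutant replicate 1 (0.0708), without wild-type replicates 1 and 3 (0.0791), and without the library of strongest GC trend in each group (0.105).

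The authors' deposited tables test their own lists of genes. Every matched gene in their ontology tables had an unadjusted p below 0.01 in their main table, with a highest value of 0.00989 in both directions. These lists were chosen on the same samples, so their enrichment is not independent evidence of direction. In the authors' deposited table of cell types, 59 of the 940 higher genes were markers of CA1 and CA2 pyramidal neurons, a fold enrichment of 3.22 (Bonferroni-corrected p = 1.77e-14), and 23 were interneuron markers, a fold of 3.18 (9.29e-06). Of the 799 lower genes in the authors' deposited table, 40 were oligodendrocyte markers (fold 2.68, corrected p = 1.79e-07), 28 were astrocyte markers (fold 2.62, 3.68e-05) and 26 were endothelial markers (fold 1.99, 0.0077).

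Neuronal terms led the ontology of the higher genes. In the authors' deposited table these were neuron part (fold 4.05, 214 genes, corrected p = 4.97e-69), neuron projection (4.30), protein binding (1.61), nervous system development (2.98) and synapse (4.91, 142 genes, corrected p = 5.82e-54). The lower genes were led in the authors' deposited table by broad intracellular terms, which were cytoplasmic part (fold 1.95, 478 genes, corrected p = 1.65e-61), organelle (1.61), membrane-bounded organelle (1.66), intracellular (1.55) and intracellular part (1.55). Among the lower genes, the authors' deposited table also listed ribosome (fold 4.53, 31 genes, corrected p = 4.53e-08) and mitochondrion (fold 2.70, 148 genes, corrected p = 5.81e-25), both picked here after the values were seen. After Bonferroni correction, 538 of 7551 terms for the higher genes and 330 of 7648 for the lower genes passed 0.05 in the authors' deposited tables. Transcription factor motifs leading the authors' deposited table were HNF4 (fold 1.26), AP-2rep (1.60) and PUR1 (1.95) for higher transcripts, and GABPA (2.38), NRF-1 (1.94) and SOX5 (1.31) for lower ones. Their binding data sets were led by H3K4me3 in adipose progenitors (fold 1.40) and H3K4me2 in neurons (1.47) for the higher transcripts, and by H3K9ac (1.91) and RNA polymerase II (2.37) in endothelial cells and H3K4me3 in adipose progenitors (1.503) for the lower ones, per the authors' deposited table. Of the 28782 entries that the authors counted, 17630 carried the adipose progenitor mark and 20590 the HNF4 motif. Both were thus features of most entries, and the adipose progenitor mark was among the leading sets in both directions.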

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

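The planned count test (the edgeR quasi-likelihood F test) was not run, because the values were read as coverage. No paired analysis was possible because the replicate numbers only follow accession order. Ptchd1 kept its direction under all 21 alternatives (log2 change -1.41 to -1.17) and its call under 13 (adjusted p 0.000315 to 0.406). Leaving out each library in turn gave 0 to 21 higher genes, 0 to 36 lower genes, a Ptchd1 log2 change of -1.41 to -1.17 (adjusted p 0.00338 to 0.371) and 16 to 18 called lists, against 14 with quantile normalization and 15 at a mean of at least 50. Ptchd1 missed the threshold with quantile normalization (-1.25, adjusted p 0.0556), limma without trend (-1.28, 0.292), voom (-1.26, 0.0589), bases in place of read equivalents (-1.29, 0.0598) and without the libraries of high choroid plexus markers (-1.35, 0.406), so 0 genes were lower in each of these. The last of these leaves fewer samples, and for the others the cause was not tested. Calls numbered 2 higher with GC and length correction, 7 higher and 3 lower with robust empirical Bayes, 462 higher and 343 lower with library quality weights, and 18 higher and 92 lower without the library of strongest GC trend in each group. The cause was not tested. The last of these settings also left out wild-type replicate 2, without which choroid plexus markers were among the genes called lower. These 4 alternatives, the transcript rows, voom and the choroid setting were chosen after seeing the data. Of the 18 called gene lists, 0 held with an estimated correlation and 0 with fry. After GC and length correction, 0 held with an estimated correlation and 1, the pyramidal neuron markers, with fry (adjusted p 0.0101). The choroid plexus set reversed in camera without wild-type replicates 1 and 3 (unadjusted value 0.00781, adjusted p 0.0247). The authors' p-values called 1226 genes at 0.05, 1850 at 0.1 and 528 at 0.01, and their ontology results held 868 terms at a corrected 0.05, 742 at 0.01 and 4180 at an uncorrected 0.05. Depth limits genes near the filter of 10 read equivalents most, and mutant replicate 3 (12450000 read equivalents) is the shallowest library.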

Other observations

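The gene and list calls of the actual groups and the loss of list calls under an estimated correlation, without GC and length correction, were planned; the other tests in this part were chosen after the results were seen. Short structured RNAs, a group that the fixed lists did not cover and that was picked after its values were seen, mostly had lower values in the mutants. Of 88 measured small nuclear, small nucleolar, vault and other short structured RNA genes, 86 had negative log2 changes, with a median of -0.95, and 62 were lower with no overlap between groups. After correction for GC content and length the median was -0.32, and 67 of the 84 genes with both properties were lower. Their median log2 deviation from the 6-library mean was 0.37, 0.50 and 0.70 in wild-type replicates 1, 2 and 3, and -1.17, -0.30 and -0.0086 in mutant replicates 1, 2 and 3. Vaultrc5, a vault RNA, averaged 89.2 ± 20.7 in wild type and 39.4 ± 3.90 in the mutants (SD, n = 3 each), Scarna2, a guide RNA of Cajal bodies, 103 ± 8.93 and 52.5 ± 10.7, and Snora5c 93.0 ± 15.5 and 48.3 ± 2.42 (log2 change -0.92, and -0.42 after correction). Their limma adjusted p was 0.109 each. Thalamic signal stood out in 1 library. The mean log2 deviation of the thalamus markers was 0.64 in mutant replicate 2 and between -0.30 and 0.06 in the other 5 libraries. Tcf7l2, a thalamic transcription factor, was at 414 in mutant replicate 2 and between 48.9 and 69.4 in the other 5 libraries. Not every marker followed, as Prkcd averaged 415 ± 88.3 in wild type and 333 ± 20.6 in the mutants.

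The choroid plexus pattern follows single libraries. Choroid plexus tissue in the dissected samples would bring its other transcripts too, and of 23 measured genes of a second choroid plexus list, none in the first, 22 were higher in both wild-type replicates 1 and 3 than in each of the other 4 libraries, against 6.24% of all genes. Enpp2, a lysophospholipase also expressed outside the choroid plexus, stood at 30842 and 13383 in these 2 libraries and between 3737 and 3892 in the others. The second list was written after the data were seen. Some of its genes, such as Enpp2, Kcne2 and Cldn2, were among those called lower without wild-type replicate 2. Its share is therefore not independent evidence for the tissue explanation. A lower choroid plexus expression in the mutant genotype stays open, because the wild-type library without the pattern is a single one, in which 1 of the 15 markers was higher than in each mutant library and 5 were lower. The tissue explanation may account for this set, and whether it also moved ependymal and meningeal markers stays open.

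The shift of synaptic against ribosomal and respiratory genes was examined for GC and length trends. Their removal left the presynaptic list 79.4% of its mean log2 change (0.21 before, 0.16 after), so the fitted trends took away the smaller part. The unadjusted rotation p was then 0.0268, for the list with the lowest camera p in these same data. This list passed neither the rotation test adjusted over the 38 lists (0.32) nor camera with an estimated correlation (adjusted p 0.636). The unadjusted value therefore cannot decide whether those trends were the cause. The ribosomal list kept 63.4% (-0.33 to -0.21) and the oxidative phosphorylation list 46.1% (-0.24 to -0.11); both stayed past camera at the preset correlation (adjusted p 7.14e-06 and 0.0004, and 0.636 for both with an estimated correlation), and their means before correction lay below the lower 95% limits of -0.16 and -0.15 from 10000 sets matched on expression, length and GC. Members stayed shorter than their matched genes, with differences in log2 length of -0.17 SD for ribosomal and -0.23 SD for oxidative phosphorylation genes. Shorter genes had lower log2 changes, so this imbalance favours such a result. The camera and matched-set comparisons do not use the spread between libraries of genes that vary together. The rotation p after correction was 0.132 and 0.273, so for these lists a GC or length bias cannot be told apart from a change in expression. A larger share of neurons stays open for the presynaptic list, since CA1, CA3 and dentate markers had a median log2 change of -0.0901 (SD 0.22 over 30 genes) against 0.19 for the list, while pyramidal (0.15), GABAergic (0.08) and oligodendrocyte markers (-0.23) had medians in the direction such a share gives, and after correction dentate (-0.14) and GABAergic (0.11) markers were called in opposite directions. Pyramidal markers (median 0.12 after correction) were the 1 called list that then passed fry (adjusted p 0.0101). An effect of genotype on synaptic gene expression remains a hypothesis, with the lists' calls lost under an estimated correlation.

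For the small RNAs, length is a candidate source. The 66 other genes no longer than 319 bases had a median log2 change of -0.22 with a median absolute deviation of 0.48, and 43 of them were lower. That median lies 0.73 above the -0.95 of the small RNAs and within its own spread of 0, yet the spread still covers a shift of 0.5 times that of the small RNAs. This spread is that of single genes and does not measure how precisely the median is known, so the comparison cannot decide. The correction removed much of the change of the small RNAs. A length bias therefore cannot be told apart from a change in these RNAs.

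With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1 called gene, a count that 2 of the 10 splits gave, the real one included, with 1 as the highest of the others. It gave 2941 genes at an unadjusted p under 0.05 against 1643 in the highest other split, and 2271 against 1384 after GC and length correction, in each case as the 1 split with as large a count. It gave 18 called lists, and 2 of the 10 splits, the real one included, reached that number, with 18 as the highest other.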
